A study of Mus musculus with 3 samples.

How the data were processed

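Nkx2.2, a homeodomain transcription factor, was measured by chromatin immunoprecipitation and sequencing in mouse oligodendrocyte progenitor cells (OPCs) and in oligodendrocytes (OLs) made from them in culture. Per the labels' protocols, the progenitors were taken from the cortex of C57BL/6 mice at postnatal day 7 with an antibody to the PDGF receptor alpha. They were grown in serum-free medium with PDGF-AA at 10 ng/mL, NT-3 at 1 ng/mL and CNTF at 10 ng/mL. Removal of PDGF-AA and addition of the thyroid hormone T3 at 40 ng/mL for 48 h gave the OLs, which no longer divide. The labels list 1.5e7 cells per library and a monoclonal Nkx2.2 antibody. The series has 3 libraries, namely OPC, OL and an input, with 1 library for each. The input library was not analysed here.

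The deposited table lists 37271 merged genomic regions on 20 chromosomes, the 19 autosomes and X. The authors joined the intervals called in the 2 ChIP libraries into regions, per the file headers, and marked for each library whether it holds a called interval. For each region the deposited table gives the average signal and the highest signal of each library. It also gives the counts of gene, promoter and CpG island features that the authors assigned to it, with the names of nearby genes and the distance and position of the region relative to each gene's start. BWA, MACS 1.4.2 and the mouse build mm9 are named in the submitters' processing notes. The calling threshold, the use of the input, the fragment extension and any scaling of signal between libraries are not given in the sources used here. Calls were made per library and not on pooled libraries. Sequencing depth is unknown, because signal values do not give read counts. Coordinates are printed as the deposited table gives them, and whether its region starts count from 0 or 1 is not stated. Regions were 574 bp long at the median, with a range of 182 to 6126 bp, and 8708 of them merged 2 intervals while 171 merged 3 or more.

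From these values the regions called in OPC, in OL and in both were counted. For each region log2((OL + 1) / (OPC + 1)) of the average signal was computed, with a pseudocount of 1 signal unit, which understates the ratio of weak regions. No filter on low signal was used. Regions with a log2 ratio of 1 or more and of -1 or less were counted. A region was placed at a promoter where the deposited distance to a gene start was within 1 kb, and otherwise in a gene, upstream, downstream or without an assigned gene, from the deposited positions. That distance runs from the middle of the region, so a long region can cover a start more than 1 kb from its middle. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error over regions only. With 1 library per cell state there are no replicates, so no test between states was run and no p-value is given. A difference between the libraries has no replicate check.

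A gene was represented by the assigned region with its highest signal in either library. Before the data were examined, 20 gene lists were fixed. They cover OPC markers, lineage transcription factors, newly formed oligodendrocyte genes, myelin genes, Nkx2.2 targets from earlier work, cholesterol synthesis, the cell cycle, the Wnt, Notch, BMP and TGF-beta and hedgehog pathways, chromatin factors and corepressors, pancreatic islet genes, ventral neural tube genes, markers of neurons, astrocytes, microglia and vascular cells, housekeeping genes, and liver and muscle genes. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on the mean signal of the gene's region in 10 ranges. That percentile describes these libraries, since genes are not replicates. In a test on simulated shifts of 14473 genes, a shift of 0.5 on the log2 scale was found in 34% of lists of 8 genes and 74% of lists of 16. A shift of 1 was found in 91% and 100% of them. This test used 100 simulated lists per setting and 500 random lists for each. It shuffled the ratios over genes, so it does not cover any link of the ratio to signal or to the number of regions.

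Gene names in the deposited table include older symbols. The RefSeq gene table of assembly GRCm38.p6 was used for names and for protein-coding status alone. Of the 14473 gene names, 13006 (89.9%) matched it. No length-matched lists were drawn for the presence of regions, because no mm9 annotation was used here. Members with a called region within 2 kb of the deposited gene start were instead set beside 10000 random lists of protein-coding genes, a comparison chosen after seeing the data. These lists were unmatched for length, CpG islands or expression.

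The genes named were chosen by rules set before the data were examined. These were the genes of the 10 highest regions in each library, and those of the 10 largest positive and negative log2 ratios among regions above the median mean signal with an assigned gene. Every member with a region of the 5 lists on the lineage and on earlier Nkx2.2 targets qualified, and of each other list at most the 4 members with the highest signal. The alternatives tried were stricter signal thresholds, other definitions of a shared region, leaving out chromosome X, rescaling of the libraries, peak in place of average values, other pseudocounts, a filter on weak regions, a wider promoter window and other ways to choose and match a gene's regions. Some genes that these rules select are not reported here. The NK2 motif search planned for the regions was not run, as no mm9 sequence was used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.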

Results

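Nkx2.2 occupancy was mapped in cultured mouse OPCs, the dividing progenitors of the oligodendrocyte lineage, and in the postmitotic OLs obtained from them after 48 h without PDGF-AA and with T3. The series asked where in the genome the factor binds in each of these states. Each state has 1 ChIP library, so the differences given here lie between 2 libraries and have no replicate check. Values are the deposited average signal per region, on the scale the authors left them, and the depth of the libraries is unknown.

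Nkx2.2 regions were found in both states, and more were called in OLs. The OPC library had 14370 called regions and the OL library 31780, which is 2.21 calls in OL for each call in OPC. Most OPC calls, 8879 or 61.8% (95% interval 61.0 to 62.6%), lay in regions also called in OL, while these made up 27.9% (27.4 to 28.4%) of the OL calls. A further 22901 regions were called in OL only and 5491 in OPC only. The ratio of OL to OPC calls lay between 2.03 and 2.38 on each of the 20 chromosomes. With all 14370 OPC calls kept and the OL calls cut to as many of the strongest, 39.4% of each set were shared.

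**Figure D1:**
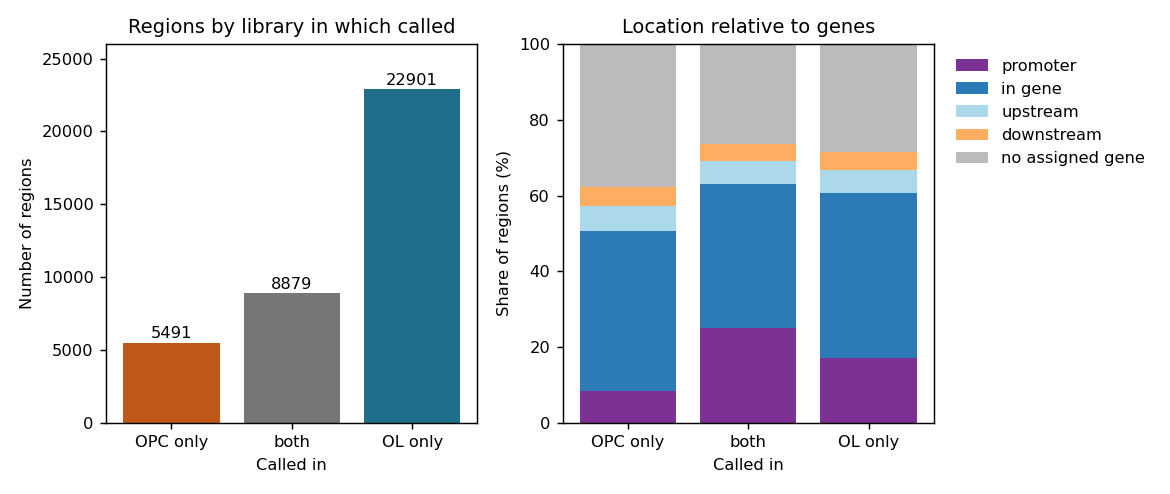
Left, the number of regions called in the OPC library only, in both and in the OL library only (5491, 8879 and 22901). Right, the share of each set (in percent) by position relative to genes, with promoter regions within 1 kb of a gene start making up 24.98% of the shared set and 8.52% of the OPC-only set.

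Regions called in 1 library usually held some signal in the other, which cannot be told from background, as the input was not analysed. At OL-only regions the median average signal was 5.20 in OL and 2.00 in OPC, and at OPC-only regions it was 4.89 in OPC and 2.27 in OL. Shared regions were the strongest, with medians of 5.37 in OPC and 6.73 in OL. Each of them merges at least 2 called intervals, so their greater length, 762 bp at the median, was favoured by how regions were joined. The median log2 ratio of OL to OPC signal was 0.74 over all regions, 1.12 over OL-only regions, -0.90 over OPC-only regions and 0.24 over shared regions. The opposite signs of the OL-only and OPC-only regions follow from selecting these sets by their calls. A log2 ratio of 1 or more was seen at 13991 regions and one of -1 or less at 2621. Setting the median of the shared regions to 0, a shift of 0.24, gave 10146 and 3760 regions, and setting the median of all regions to 0 gave 4909 and 6522. Each setting subtracts the same value from every region, so which group is larger depends on the scaling chosen.

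The strongest OPC region, chr6:97485919-97486504, lay inside Frmd4b and had a signal of 68.8 in OPC and 29.1 in OL. Other regions among the 10 highest in OPC lay inside Grin2b, an NMDA receptor subunit gene (55.0 and 32.4), Prdm16, a zinc finger transcription factor gene (51.0 and 27.3), Auts2 (45.4 and 48.3) and Hapln1, which encodes a link protein of the hyaluronan matrix (45.0 and 17.8). All 10 of these regions were called in both libraries. A region at chr5:92692748-92693524, inside Asahl and upstream of Ppef2, was high in both, at 57.1 in OPC and 58.2 in OL. So was the longest region, 6126 bp at chr17:39979839-39985965 and covering the start of Mirn715, at 51.2 and 60.1, the latter the highest value in OL. Whether that region is a repeated sequence was not checked, and its signal is not read as Nkx2.2 binding here. Among the 10 highest in OL, Cugbp2, an RNA-binding protein gene, had 54.2 in OL and 5.33 in OPC, Sept11, a septin gene, 48.9 and 23.6, and Arhgap18 48.8 and 11.5. Another 4 of these 10 regions had no assigned gene, the strongest of them at chr15:39951740-39952671 with 56.4 in OL and 2.57 in OPC. Of the 100 strongest regions of each library, 24 were in both sets.

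The largest differences were taken among regions with an assigned gene. Regions in Ndst3, a heparan sulfate sulfotransferase gene (31.2 in OL, chr3:123355303-123355700), Katnal2 (28.3), Sh3kbp1 (26.6), Pax2, a transcription factor gene (20.3), Usp37 (19.2) and Vprbp (18.0) were listed at 0 in OPC. The same held for a region in Axin2, a feedback inhibitor of Wnt signalling (17.7 in OL, chr11:108786955-108787321), and for regions upstream of Marveld1 (19.0) and 5730469M10Rik (23.3). A region in 2900041A09Rik had 50.0 in OL and 1.71 in OPC. In the opposite direction, a region downstream of Lpin1, a phosphatidate phosphatase gene, had 13.3 in OPC, and one in Dlgap2, upstream of Erich1, had 10.96, and both were listed at 0 in OL. Slco1c1, which encodes a thyroid hormone transporter, had 17.3 in OPC and 1.35 in OL at chr6:141516611-141517540. Rbms1, an RNA-binding protein gene, had 26.9 and 3.71, and Kif5c, a kinesin gene, 11.4 and 1.11. The rest of the 10 regions lower in OL were assigned to EG665239, D230012E17Rik, LOC100040253, 1700081D17Rik and LOC100042715. No region of these sets of 10, nor of the highest 10 in either library, had its middle within 1 kb of a gene start. The 6126 bp region on chromosome 17 still covers the starts of LOC627695 and Mirn715, 1091 and 1822 bp from its middle.

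Over all regions, gene bodies held the most calls and promoters took different shares of the sets. Of the 37271 regions, 15661 lay in a gene, 6614 within 1 kb of a gene start, 2275 farther upstream, 1792 downstream, and 10929 had no assigned gene. The authors' own promoter feature was assigned to more regions, 9826, and the promoter shares given here do not use it. Promoter regions made up 24.98% (24.1 to 25.9%) of the shared set, 17.2% (16.7 to 17.7%) of the OL-only set and 8.52% (7.80 to 9.29%) of the OPC-only set. CpG islands followed the same order, at 24.9%, 17.8% and 7.99% of regions. OPC-only regions had the highest share without an assigned gene, 37.8% (36.5 to 39.1%), against 26.5% (25.6 to 27.4%) of shared regions. Taken by library, promoters held 18.7% of OPC calls and 19.3% of OL calls. With the calls of a library split by signal into 10 equal groups, promoters held 4.87% of the strongest group in OPC and 9.63% in OL, and 26.9% of the weakest group in OPC. In OL the share did not keep rising toward weak calls, with 22.8% of the fifth group and 13.3% of the weakest. In both libraries the strongest group was the most often shared, at 83.9% in OPC and 59.4% in OL.

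**Figure D2:**
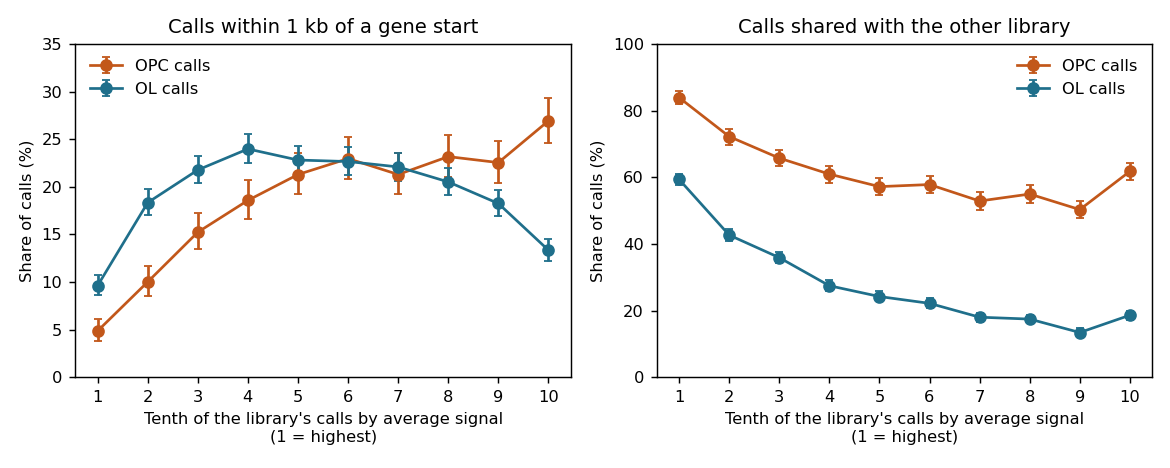
Calls of each library in 10 equal groups by average signal (x axis, 1 is the strongest), with the share in percent that lies within 1 kb of a gene start (left) and the share also called in the other library (right), and exact 95% intervals over regions as bars. Promoter calls make up 4.87% of the strongest group in OPC and 9.63% in OL, and shared calls 83.9% and 59.4%.

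Most genes that mark OPCs carried Nkx2.2 calls in both states, and 3 of the 5 regions at Olig1 had more OPC signal. Values given for a gene are those of its highest region unless said otherwise, and its other regions can differ. All 20 OPC markers had a region, 17 of them a call in OPC and all 20 a call in OL. Of all protein-coding genes, 32.9% had a region called in OPC and 53.9% one called in OL. Counts of members with a call are not matched for gene length in any list. The median log2 ratio of the OPC markers was 0.73, the same as the median of 0.73 over the 14434 genes with a region, and at percentile 64.4 of matched random lists. Among lists matched also on the number of regions the percentile was 34.6, so its side of the middle depends on the matching. A ratio of 1 or more was seen at 5 markers and of -1 or less at 2, Olig1 and Ncan. Olig1, a basic helix-loop-helix factor of the lineage, had 20.7 in OPC and 4.44 in OL at a region 6576 bp upstream of its start (chr16:91262727-91264150), and 15.2 and 2.81 at another 3581 bp upstream. A region between them had 4.92 and 1.46, while the other two, called in OL only, had 1.89 and 4.63 upstream and 4.17 and 5.39 downstream of the gene. Its neighbour Olig2, which specifies the lineage, had 7.12 and 7.85 at its highest region and 6.88 and 5.73 at its start. Ncan, which encodes the proteoglycan neurocan, had 8.83 in OPC and 3.00 in OL.

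Pdgfra, the receptor for the mitogen that keeps OPCs dividing, differed along its length. A region 11173 bp into the gene (chr5:75558985-75559993) had 8.30 in OPC and 24.3 in OL, a log2 ratio of 1.44. At the region on its start, chr5:75547849-75548653, the values were 7.60 and 2.33, a log2 ratio of -1.37. Cspg4, the gene of the NG2 proteoglycan, had 17.2 in OPC and 23.5 in OL. Tnr, a gene for the matrix protein tenascin-R with 35 regions, had 1.43 and 17.5 at its highest and a mean log2 ratio of 0.94 over them, and Sox6 had 14.1 and 9.29 at its highest, while 17 of its 31 regions were called in OPC and 26 in OL. Hes5, a target of Notch signalling, had 3.64 and 10.7, and Lhfpl3 6.72 and 14.6.

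**Figure D3:**
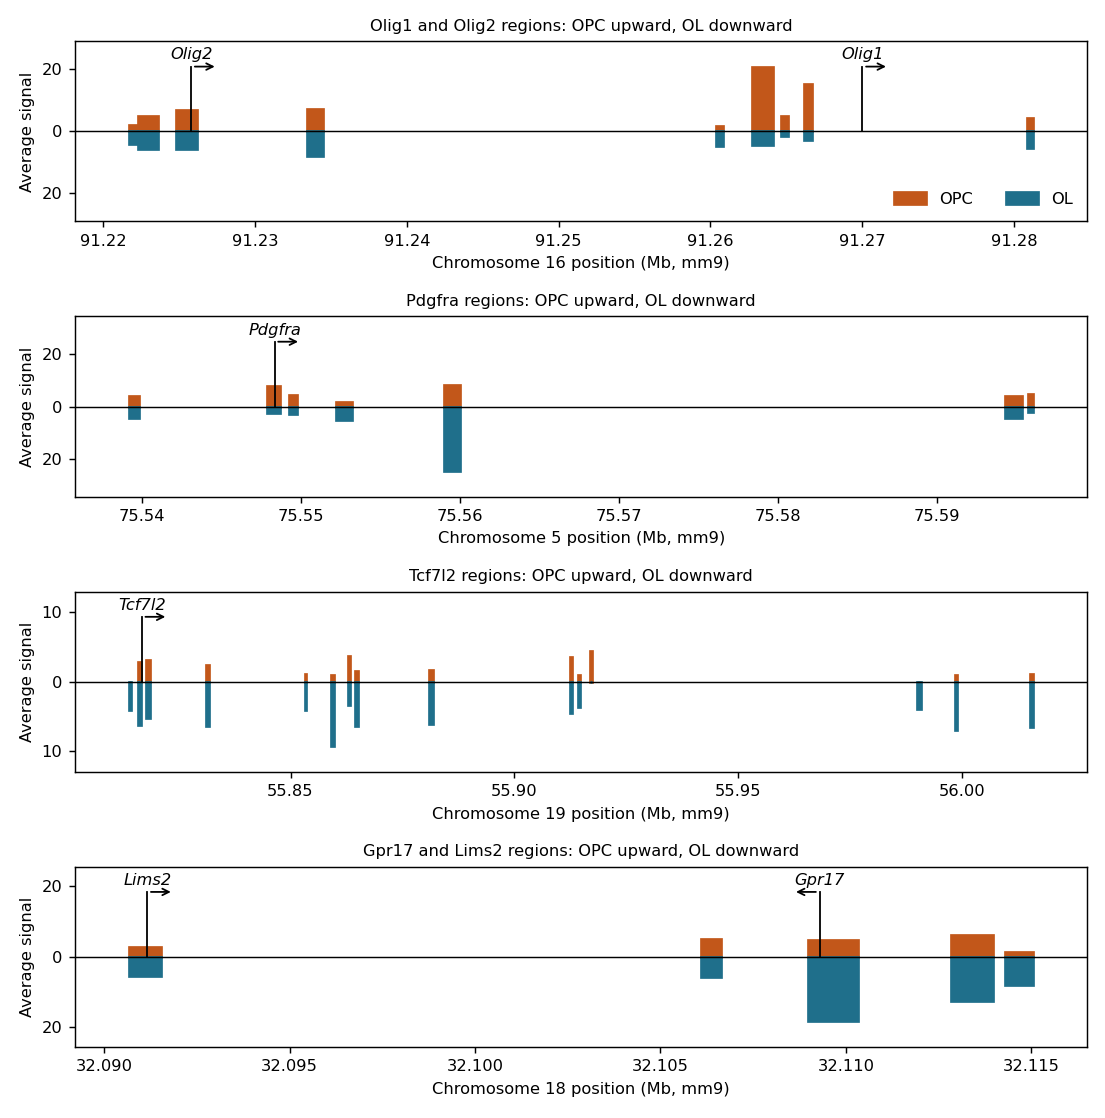
Average signal (y axis) of the OPC library (upward bars) and the OL library (downward bars) at the regions assigned to Olig1 and Olig2, Pdgfra, Tcf7l2, and Gpr17 and Lims2, by position in Mb on mm9, with arrows at gene starts placed from the deposited distances. The region upstream of Olig1 has 20.7 in OPC and 4.44 in OL, and the highest region in Pdgfra 8.30 and 24.3.

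Most genes of the lineage's own transcription factors also had calls in both states, the gene of Nkx2.2 included. Of 25 factors 24 had a region, all but Nkx6-1, with calls in OPC at 19 and in OL at 23. The median log2 ratio was 0.68, at percentile 41.6 of matched lists, with 8 members at 1 or more and 2 at -1 or less. With matching also on the number of regions the percentile was 15.6. Nkx2-2 had 4 regions, with 5.13 in OPC and 9.20 in OL at the highest (chr2:147006070-147007205). Among the factors with more OL signal, Tcf7l2, a Wnt effector expressed as OPCs begin to differentiate, had 9.29 in OL and 1.00 in OPC, and 15 regions. Myrf, which drives transcription of myelin genes and is listed as Gm98, had 6.13 in OL and 1.00 in OPC and no OPC call. St18 had 14.9 and 1.43. Nfia had 9.86 and 1.00, but over its 16 regions, 6 called in OPC and 12 in OL, the mean log2 ratio was 0.35. Nkx6-2 had 4.69 at its start and was listed at 0 in OPC. Sox10, which is needed for terminal differentiation, had 7.26 in OL and 5.78 in OPC at its highest region, downstream of the gene, and 6.98 and 1.83 at its start. Sox8 had 1.56 in OL and 6.61 in OPC at its highest region, also downstream, but 4.91 and 2.56 at its start.

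Of the lists on the lineage, the genes of newly formed oligodendrocytes stood farthest toward the OL library. Regions were present at 16 of 17, all but Casr, with OPC calls at 14 and OL calls at 16. The median log2 ratio was 1.65 against 0.73 for all genes, at percentile 99.99 of lists matched on signal, whose central range was 0.27 to 1.13. With the mean of all regions of each gene, the median was 0.99, at percentile 97.85 of lists matched on signal. At the highest region, ratios of 1 or more were seen at 12 members and of -1 or less at 0. Fyn, a kinase gene with 16 regions, had 11.6 in OL at its highest region and was listed at 0 there in OPC, with a mean log2 ratio of 1.13 over all its regions. Enpp6, a choline phosphodiesterase gene, had 11.3 in OL and 1.88 in OPC, and Itpr2, an inositol trisphosphate receptor gene with 12 regions, 14.6 and 3.27. A region at chr18:32108977-32110341, 369 bp upstream of Gpr17 and inside Lims2, had 18.2 and 4.89, and a region of Sirt2 had 19.7 and 8.28. Samd4b had 17.2 in OL and 3.33 in OPC, and a mean log2 ratio of 0.68 over its 4 regions. Tmem2 had less signal in OL than in OPC, with 6.72 and 10.6. The highest region of Frmd4a had 26.4 in OL and 28.3 in OPC, while over its 22 regions, 18 called in OL and 8 in OPC, the mean log2 ratio was 0.78. These genes had a median of 4.5 regions each against 2 for all genes, and among lists matched also on the number of regions, a comparison chosen after seeing the data, the percentile was 97.94, and 95.51 to 98.115 with 1 member left out.

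A smaller part of the myelin genes had a region than of the lists above, and most of those had more OL signal, 19 with a ratio above 0 and 2 below. Most regions overall also had more OL signal, 28855 of 37271. Of 28 genes 21 had a region, 14 with a call in OPC and 20 in OL. Those without one included Mag, Ermn, Aspa and Plekhh1. The median log2 ratio of 1.01 lay at percentile 95.4, inside the central 95% of matched lists, with 11 members at 1 or more and 0 at -1 or less. Among lists matched also on the number of regions the percentile was 89.9. Mal, a gene for a proteolipid of myelin membranes, had 13.0 in OL and 3.18 in OPC. Nfasc, a gene for an adhesion protein of the node and paranode, had 13.7 and 3.75, and Plekhb1 17.3 and 3.31. Mbp, the myelin basic protein gene, had 9 regions, with 9.46 in OL and 5.75 in OPC at the highest. Mog had 4.67 and 6.17, with a call in OPC and not in OL, and Cnp, listed as Cnp1, had 11.8 and 4.63.

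Of 9 genes that earlier work named as Nkx2.2 targets, 8 had a region, all but Ins1, with calls in OPC at 5 and in OL at 8. They include Pdgfra, Mbp, Sirt2 and Nkx2-2 itself, given with the lists above, and genes of the pancreatic islet, where Nkx2.2 also acts. Neurod1, a basic helix-loop-helix factor gene, had 1.00 in OPC and 4.30 in OL, Mafa 1.93 and 4.65, and Ins2 1.67 and 3.86. The median log2 ratio was 0.91, at percentile 66.7. Ratios of 1 or more were seen at 3 members, Pdgfra, Neurod1 and Sirt2, and of -1 or less at 0.

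Among signalling pathways, Wnt genes had regions at 28 of 31 members, 14 called in OPC and 27 in OL, with a median log2 ratio of 0.71 (percentile 38.9). Ctnnb1, the gene of beta-catenin, had 16.7 in OL and 6.27 in OPC, and the coreceptor gene Lrp6 15.1 and 6.19. Notch genes had regions at 22 of 24, 12 in OPC and 22 in OL, with a median of 0.69 (percentile 37.3). Notch2 had 26.3 in OPC and 15.7 in OL at its highest region, but all 5 of its regions were called in OL and 2 in OPC, with a mean log2 ratio of 0.66. Notch3 had 2.00 in OPC and 21.4 in OL. BMP and TGF-beta genes had regions at 21 of 28, 8 in OPC and 21 in OL, with a median of 0.72 (percentile 39.4). Smad1 had 19.4 in OPC and 12.2 in OL at its highest region, and a mean log2 ratio of 0.13 over its 3 regions. Hedgehog genes had regions at 11 of 13, all 11 called in OPC and 9 in OL. Their median of 0.01, at percentile 0.875, became -0.23 after rescaling on the shared regions, and the percentile was 16.7 with the mean of all regions of a gene. Ptch1, the hedgehog receptor gene, had 19.8 in both libraries at its highest region. Gli2, a transcription factor of the pathway, had 12.9 in OPC and 4.96 in OL at its highest region, but all 9 of its regions were called in OL and 2 in OPC, with a mean log2 ratio of 1.08.

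The lists for metabolism, division, chromatin and other tissues lay inside the central 95% of their random lists. Cholesterol synthesis genes had regions at 15 of 20, 12 in OPC and 15 in OL, with a median log2 ratio of 0.63 (percentile 36.0). Srebf2, their main activator, had 12.8 in OL and 1.78 in OPC. Cell cycle genes had regions at 19 of 25, 14 in OPC and 19 in OL, with a median of 0.63 (percentile 36.7). Top2a, a topoisomerase gene, had 28.1 in OL and 3.32 in OPC at a region 995 bp upstream of its start, and Cdk6 3.94 and 11.6. Chromatin factors and corepressors had regions at 18 of 19, 11 in OPC and 18 in OL, with a median of 0.54 (percentile 21.5). Tle3, a gene for a Groucho corepressor of the kind that Nkx2.2 recruits, had 13.5 in OL and 2.00 in OPC, but 6 of its 8 regions were called in OPC and 7 in OL, with a mean log2 ratio of 0.68. Ventral neural tube genes had regions at 9 of 19, 4 in OPC and 9 in OL, with a median of 0.73 (percentile 41.1). That list also holds Pax7, which is not a ventral marker, with 20.9 in OPC and 16 in OL. Pancreatic islet genes had regions at 10 of 20, 4 in OPC and 9 in OL, with a median of 0.78 (percentile 44.7). Insm1 had 9.65 in OPC and 4.0 in OL.

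Markers of other cells the cultures could hold differed in how many members had a region, from 13 of 14 astrocyte markers to 5 of 13 vascular markers. Astrocyte markers had calls at 9 members in OPC and 12 in OL, with a median log2 ratio of 0.84 (percentile 73.2). Slc1a3, a glutamate transporter gene, had 16.1 in OPC and 5.17 in OL, with a mean log2 ratio of -0.38 over its 9 regions, and S100b had 5.40 and 15.7. Neuron markers had regions at 12 of 21, 8 in OPC and 11 in OL, with a median of 0.60 (percentile 26.5). Map2 had 12.7 in OPC and 12 in OL. Microglia markers had regions at 6 of 14, 4 in OPC and 6 in OL, with a median of 0.23 (percentile 8.55) that became -0.016 after rescaling on the shared regions. Vascular markers had calls at 3 members in OPC and 2 in OL, with a median of -0.60 (percentile 0.535). With 1 of the 5 members left out this median lay between -0.93 and -0.017, and the latter is inside the range of its random lists, which starts at -0.18. Kdr had 26.1 in OL and 2.43 in OPC, while Des had 2.36 and 7.0. Housekeeping genes had regions at 15 of 18, 11 in OPC and 15 in OL, with a median of 0.80 (percentile 73.9), and Rplp0 had 16.4 in OL and 9.41 in OPC. Liver and muscle genes had regions at 9 of 20, 6 in OPC and 7 in OL, with a median of 0.34 (percentile 7.89). Over the 20 lists, 1 would lie outside the central 95% of its random lists by chance. The lists outside were the newly formed oligodendrocyte genes above, and the hedgehog and vascular lists below.

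**Figure D4:**
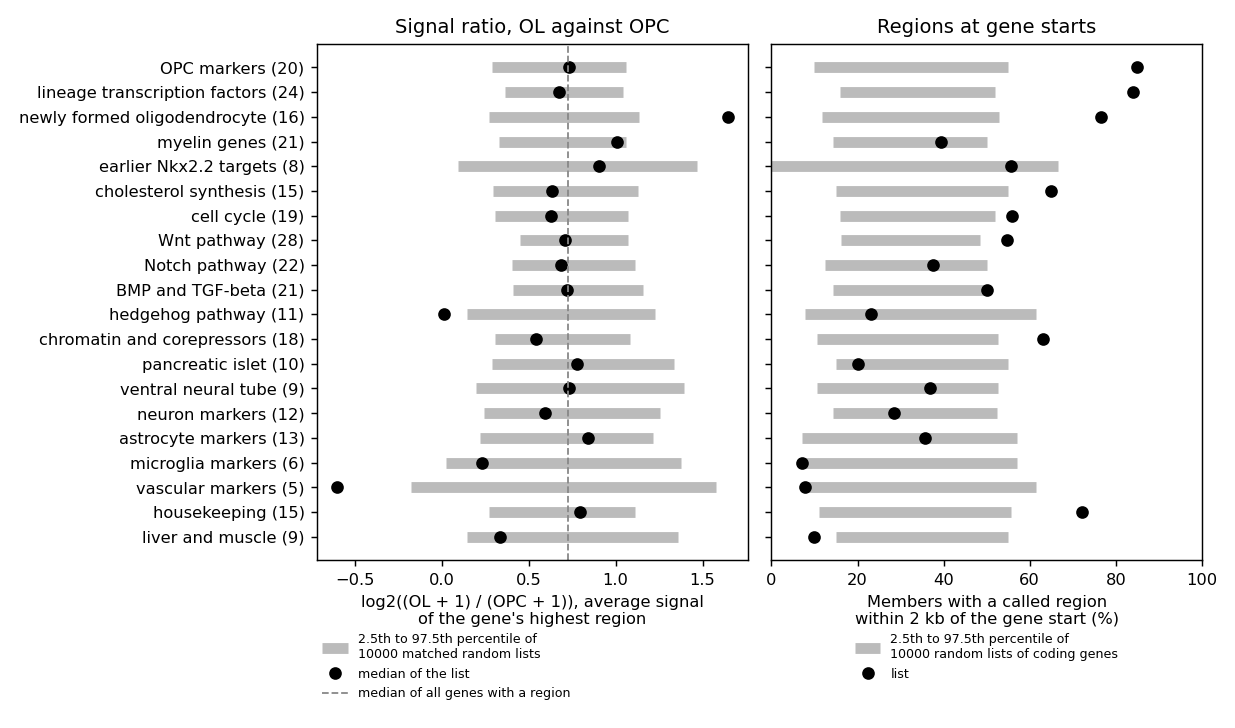
Left, the median log2((OL + 1) / (OPC + 1)) of each list (points, members with a region in brackets) beside the central range of 10000 matched random lists (grey) and the median of all genes with a region (dashed), with the newly formed oligodendrocyte list at 1.65. Right, the share of members with a called region within 2 kb of the gene start (in percent) beside the range of random lists of protein-coding genes, from 85.0% for OPC markers to 7.14% for microglia markers.

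Near gene starts, OPC markers, lineage factors and newly formed oligodendrocyte genes were well represented, as were housekeeping genes. A called region within 2 kb of the start was present at 17 of 20 OPC markers, 21 of 25 lineage factors and 13 of 17 newly formed oligodendrocyte genes. Among random lists of protein-coding genes these counts lay at percentiles 100, 100 and 99.995. For 11 of 28 myelin genes and 5 of 9 earlier Nkx2.2 targets the percentiles were 79.3 and 92.3. Housekeeping genes (13 of 18, percentile 99.925), cholesterol synthesis (13 of 20, 99.865), chromatin factors (12 of 19, 99.6), Wnt (17 of 31, 99.4) and the cell cycle (14 of 25, 99.2) were also high. BMP and TGF-beta genes had 14 of 28 (97.3), Notch genes 9 of 24 (71.7), ventral neural tube genes 7 of 19 (68.7), astrocyte markers 5 of 14 (62.6), neuron markers 6 of 21 (38.1), hedgehog genes 3 of 13 (26.3) and islet genes 4 of 20 (12.8). The lowest counts were those of vascular markers (1 of 13, percentile 2.65), microglia markers (1 of 14, 1.96) and liver and muscle genes (2 of 20, 1.36). The random lists were not matched for CpG islands or expression, so these percentiles do not show that Nkx2.2 prefers the genes of a list. Over all 21900 protein-coding genes, 7012 or 32.0% (31.4 to 32.6%) had a called region there, 3110 in OPC and 6596 in OL. Both libraries had one at 2694 genes, where independent sets of these sizes would share 937. Independence ignores traits that gene starts share, such as CpG islands, held by 83.3% of regions within 1 kb of a start. The excess alone therefore does not show shared targets of Nkx2.2.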

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

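The matching on region number, the count of each region once and the random lists for gene starts were chosen after seeing the data, and the other settings were set before the data were examined. Of the values that answer a comparison, 47 stayed within their spread, or within 1.5 times for a count, and 38 moved. Of the values for the other gene lists, 78 stayed, 40 moved and 2 changed sign. Above the median signal there were 8765 OPC and 16759 OL calls, of which 78.8% and 41.2% were shared. In the top 25% by signal there were 5242 and 8644 calls, of which 4581 were shared, or 87.4% and 53.0%. With equal numbers of calls, 14370 of each library, 5655 or 39.4% were shared. Counting a region as shared where the lower signal was at least 50% of the higher, whatever the calls, gave 16125 shared regions, which include 67.1% of OPC and 43.6% of OL calls. These settings keep fewer calls or redefine sharing by construction, and leaving out chromosome X moved none of these values beyond its interval.

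The median log2 ratio over regions, 0.74 as deposited, was 0.49 with the median of shared regions set to 0, 0 by construction with that of all regions set to 0, 1.00 with peak values, 0.82 with a pseudocount of 0.5, 0.41 with a pseudocount of 5, and 0.56 above the median mean signal. Regions with a ratio of 1 or more numbered 4909 with all regions set to 0, 3250 with a pseudocount of 5 and 5708 above the median mean signal. Those with -1 or less numbered 6522, 366 and 1020 under these settings and 4016 with peak values. Rescaling on the shared regions turned the hedgehog median from 0.01 to -0.23 and the microglia median from 0.23 to -0.016, by subtracting the same 0.24 from every region. Above the library's median signal, 14.0% of OPC calls were at a promoter, and with a window of 5 kb 26.9% of OPC and 27.7% of OL calls were. Within 2 kb of the gene start, OPC calls remained at 11 OPC markers, 7 newly formed oligodendrocyte genes and 3 myelin genes, and OL calls at 10 myelin genes and 4 earlier Nkx2.2 targets. Above the median signal, OL calls remained at 5 of the earlier targets. A larger pseudocount draws every ratio toward 0, and a filter or a limit near the gene start can only lower a count. A wider promoter window can only raise a share. These shifts and those stated above follow from construction, and the cause of the others was not tested. The median ratio of the newly formed oligodendrocyte list was 0.92 to 1.58 under the alternatives. Input subtraction was not run, as no input column was analysed here, nor were the motif settings. No paired analysis was possible because each state has 1 library, which also left no library to leave out. Depth is unknown, so how weak a region each library could detect is unknown too.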

Other observations

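The lists of strongest gene starts, of genes with the most regions and of longest regions, and the tests of the number of OL calls, were chosen only after the results were seen, and the matching on region number and the count of each region once after seeing the data. Among regions within 1 kb of a gene start, the strongest in OPC was at Plekha7, which encodes a protein of cell junctions, with 32.1 in OPC and 16.4 in OL. Card10, a gene for a scaffold of NF-kappaB signalling, had 18.8 in OPC and 3.00 in OL. Starts high in both libraries included those of Rps21, a ribosomal protein gene (23.3 and 28.1), Ccdc12 (22.7 and 34.6), Map3k3 (18.2 and 27.6) and Xab2 (16.7 and 24.8). In OL the starts of Plec1, the gene of the cytoskeletal linker plectin (5.0 in OPC and 32.2 in OL), and of Tmed2 (10.3 and 24.2) were among the 10 strongest.

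The numbers of regions per gene are not adjusted for gene length. Opcml, a cell adhesion gene, had 46 regions, 19 called in OPC and 39 in OL, and Csmd1 had 29, with 7 and 27. Pde4d, a cAMP phosphodiesterase gene, also had 29, with 10 and 24, and Nlgn1, the gene of the postsynaptic protein neuroligin, had 27, with 13 and 20. The longest region after the one at Mirn715 was in Mid1 on chromosome X (3418 bp, 10.4 in OPC and 5.61 in OL) and was called in OPC only. The next was at chr16:43464303-43467357 without an assigned gene (6.03 and 8.01). Whether either is a repeated sequence was not checked.

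The first pattern is the larger number of OL calls. A single scale factor applied to the signal would give the same ratio of OL to OPC signal at every rank. The ratio was 1.20 at rank 100 and 1.45 at rank 3000, a quotient of 1.20 (1.13 to 1.33 over resampled regions). So no single rescaling of these values makes both ranks match. This does not decide on a difference in depth, because the regions were selected by the calls and the resampling covers regions only. Weak calls near the threshold stay open: OL had 2.63 times as many regions as OPC with a signal of 10 or more (3488 against 1324), but this depends on the unknown scaling. After rescaling on the shared regions the ratio was 1.66 at a signal of 5 or more, 1.61 at 10, 1.42 at 15, 1.29 at 20 and 0.667 at 30. A better immunoprecipitation or a deeper library in OL and a wider binding of Nkx2.2 in differentiated cells cannot be told apart, because there is 1 library per state, and either may account for it.

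The second pattern is the higher OL signal at genes of newly formed oligodendrocytes. Among lists matched on signal alone, counting each region once left it at percentile 99.925, and the lowest median with 1 member left out was 1.58, above the 1.13 that bounds their central 95%. With the mean of all regions of a gene in place of its highest, the percentile was 97.85, close to the edge of the central 95%. Among lists matched also on the number of regions the percentile was 97.94, but leaving out 1 member gave 95.51 to 98.115, inside the central 95% for 7 of the 16 members, including Gpr17 (95.82) and Lims2 (95.665), which share a region. The number of regions to choose from, the shared region and the weight of single members therefore all stay open. The outcome rests on how random lists are matched and on how the regions of a gene are combined. A binding of Nkx2.2 that follows the first steps of differentiation may be a part of the pattern and remains a hypothesis, untested against other libraries.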
